A study of Mus musculus with 6 samples.

How the data were processed

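Gene expression was measured in the liver of wild-type mice (3 samples) and of mice lacking SIRT7 (3 samples), each on its own 1-colour Affymetrix expression array. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase I, purified over spin columns and converted to biotinylated cRNA, and every animal was kept under the same treatment conditions. The labels give neither strain, age, sex nor diet, no time of day at dissection and no hybridisation batch. Samples were grouped by the Sirt7 allele and the sample titles, and are called livers in the text.

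The authors deposited 1 expression value per probe set and array, calculated with GCRMA 2.20.0 in R 2.11.1, per the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, by default normalizes the arrays to each other by quantiles, and summarizes the probes of a probe set. The deposited values are on a log2 scale, read from their range of 0.841 to 13.969; the GCRMA settings are not given in the sources used here. The background model pulls unexpressed transcripts to values near the lower end, where differences between log2 values are not proportional to RNA amounts. Array medians lay between 5.69 and 5.77, 36.6% to 37.2% of the probe sets of each array were under 4, and 0 pairs of arrays held identical values. The values carry no detection call, so a low value was not tested against background. For arrays, the number of samples limits the precision.

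Probe sets were named through the platform annotation supplied with the data. Of 22626 probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none or were not listed. The gene identifiers of 20351 of the probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was otherwise used for the order of genes along chromosomes and to look up list entries not found on the array as written. Each of the 12393 genes was represented by its probe set with the highest mean over the 6 arrays, and genes whose mean log2 value was under 4 were left out, which left 8343 genes. Where another probe set of a named gene with a mean of at least 4 pointed in the other direction, its value is given. Below that level, second probe sets of Usp36 (0.17) and Fmo2 (-0.19) pointed the other way from the ones used. Probe sets with several symbols or none were tested separately, and 0 of 1160 passed the threshold with limma, against 80 at an unadjusted p under 0.05.

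Knockout was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2-sided), without further normalization and without a replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The residual degrees of freedom were 4, the prior degrees of freedom 4.6 and the median residual SD 0.282 log2 units. Errors of differences are limma's moderated standard errors, intervals are 95% confidence intervals, and group errors are SD over 3 livers. The labels do not state in so many words that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

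Gene lists for pathways, complexes, sex-biased and circadian genes and markers of the cell types a liver sample could hold were written before the data were examined, as were the comparison, the alternatives and the rule for named genes. They hold 1146 entries, 972 of them on the array, in 41 lists. Lists with at least 5 tested genes, 37 in all, were compared with the remaining genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 37 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, in 1 direction without comparing them with other genes, were run as alternatives. In all other alternatives, among them the fits without 1 array, list p-values are camera's at the preset correlation. That setting takes the members of a list as nearly independent, so small p-values there do not measure the spread over livers alone. The lists with fewer tested genes (Y-linked genes, Xist, pancreatic acinar markers, and muscle and mesothelial markers) are given as values. Within a list, the p-values of its members were also adjusted over the list alone.

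The rule for named genes took Sirt7 and Myc, the 12 largest rises and falls among called genes with non-overlapping groups or, where fewer than 5 genes passed in a direction, the 5 with the smallest p in that direction, and up to 4 members with the smallest p of each list that passed its test or held a called member. Hspa5, Ddit3, Xbp1, Fasn, Scd1, Cd36, Pparg, Rps20, Rps7, Rps14, Nme1, Cops2, Xist and Ddx3y were always included. No probe set with 1 symbol was used for Ddx3y. Genes outside the rule, among them Eif2s3y, Mcm5, Mcm7, Ranbp1 and Tfrc, were chosen after their values were seen.

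The alternatives were no filter on dim genes, a filter at a mean log2 value of 6, the mean of a gene's probe sets, each probe set on its own, a trended and robust prior, centring on array medians, a further quantile normalization, the replicate number as a block, array weights, an ordinary 2-sample test per gene, other thresholds, and leaving out each array. Centring and quantile normalization moved the median log2 change of all genes from -0.032 to -0.007 and -0.005. The fit was tested on simulated data with 8343 independent genes at the measured spread, of which 200 were changed, in 20 simulations. It called 41% of genes changed 2-fold, 86.4% of those changed 4-fold and 98.3% of those changed 16-fold. Of its calls, 4.8% were false. Changed genes were picked at random and no simulated array was atypical, so large changes did not come with large spread. These shares do not hold for genes that vary strongly within a group. Rgs16 (16.88-fold, wild-type SD 1.64) and Cyp2c39 (20.21-fold, wild-type SD 2.57) were not called in the livers. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.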

Results

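Liver RNA of wild-type mice and of mice lacking SIRT7, a nuclear member of the sirtuin family of NAD-dependent deacylases, was profiled on 6 arrays, with 3 samples per group. The study's title links SIRT7 to MYC activity and tumorigenesis, so the comparison asks how the liver transcriptome, and MYC-related genes in it, differ without SIRT7. Across the tested genes, Pearson correlations were 0.962 to 0.984 between arrays of the same group and 0.949 to 0.979 between arrays of different groups. Wild-type replicate 3 correlated better with the knockout arrays (0.972, 0.977 and 0.979) than with the other wild-type arrays (0.968 and 0.971). On the first principal component of the tested genes (45.7% of the variance) it lay at 5.9, against -25.1 and -28.3 for wild-type replicates 1 and 2 and 36.2, 16.4 and -5 for knockout replicates 1 to 3. These correlations are across genes, which are not independent replicates. All 6 livers expressed the Y-linked gene Eif2s3y (log2 value 11.03 ± 0.16 in wild type and 11.03 ± 0.38 in knockout, SD, n = 3 each). Xist, the RNA of the inactive X chromosome, was under the expression filter (3.70 ± 0.62 and 2.90 ± 0.70).

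Sirt7 mRNA was the most clearly altered transcript, at a log2 value of 9.74 ± 0.15 in wild-type livers and 2.78 ± 0.37 in knockout livers (SD, n = 3 each). It fell by 6.96 on the log2 scale (SE 0.23, limma adjusted p = 3.99e-06) and was lower in 3 of 3 knockout livers. Cxcl14, which encodes a chemokine, was the other gene that passed the threshold. It fell by 3.03 (SE 0.29, 8.18-fold, adjusted p = 0.0142), from 8.35 ± 0.31 to 5.31 ± 0.51, with every knockout value under every wild-type value, and its second probe set differed by -3.59. Sirt7 is measured by 1 probe set, and whether that probe set lies in the deleted part of the gene is not given in the sources used here.

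Limma called 2 of 8343 genes, 0 higher and 2 lower in knockout livers. At an unadjusted p under 0.05 there were 254 higher and 285 lower genes, 539 in all against 417 by chance, and an ordinary 2-sample test on the same values called 0 genes after adjustment and 405 before. The groups did not overlap in 813 genes (9.7%, against 10% by chance). The Cxcl14 call was lost without knockout replicate 2 (adjusted p = 0.0901), without knockout replicate 3 (0.0677) and with the mean of its probe sets (0.0754). The number of called genes was 38 (30 higher, 8 lower) without wild-type replicate 3 (13 of them on the cell cycle list, all higher), 7 without wild-type replicate 2, 5 without knockout replicate 1, and 1 without knockout replicate 2 or 3.

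Among the remaining genes with the smallest p toward lower values, Cd300ld, a myeloid cell-surface receptor gene, differed by -2.25 (SE 0.27, limma adjusted p = 0.0535). Pcyt2, which encodes an enzyme of phosphatidylethanolamine synthesis, differed by -3.88 (SE 0.51, adjusted p = 0.0875), at 11.45 ± 0.16 in wild type and 7.57 ± 1.21 in knockout. Usp36, a nucleolar deubiquitinase gene, differed by -1.41 (SE 0.22, adjusted p = 0.213). Toward higher values the smallest p belonged to Dntt, the template-independent DNA polymerase of lymphocyte precursors (1.46, SE 0.23, adjusted p = 0.213), and to Mcrip1 (1.15, SE 0.19, adjusted p = 0.213). Rgs16, a regulator of G protein signalling, differed by 4.08 (SE 0.76), Hspa1b, an inducible HSP70 gene, by 1.04 (SE 0.19), and Rnf186, a ubiquitin ligase gene, by 1.46 (SE 0.28), each at an adjusted p of 0.398. In the gene order of assembly GRCm38.p6, Pcyt2 is next to Sirt7 among the tested genes, Mcrip1 is 5 genes away, Usp36 27 and Cd300ld 76. Cd300ld passed the threshold without wild-type replicate 2 (adjusted p = 0.00762) or 3 (0.0338), and Pcyt2 passed without knockout replicate 1 (0.00127). Toward higher values, Rgs16 passed without wild-type replicate 2 (5.02, adjusted p = 0.0072) and Dntt without wild-type replicate 3 (1.65, adjusted p = 0.0259).

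**Figure D1:**
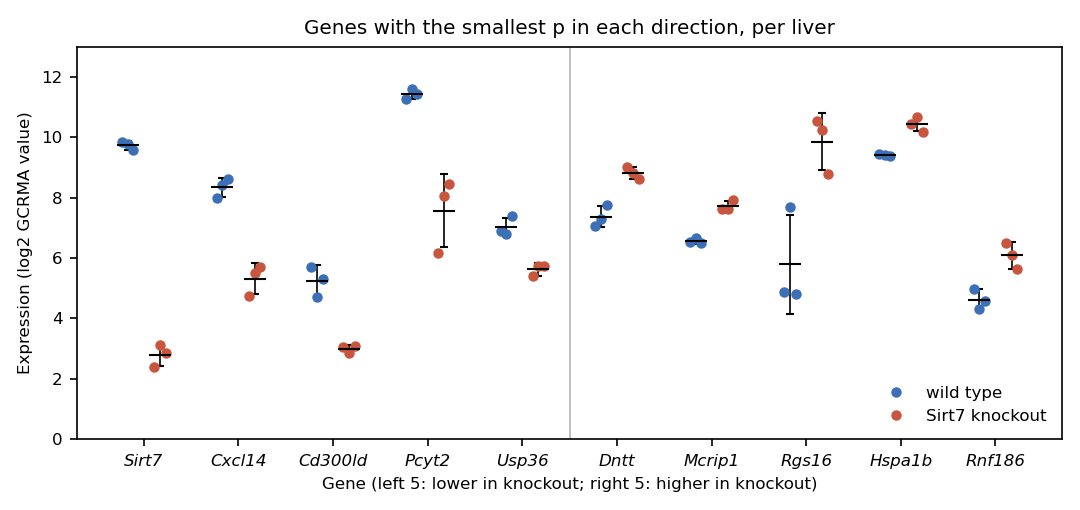
Log2 GCRMA values of the 5 genes with the smallest p in each direction, 1 point per liver (blue, wild type; red, Sirt7 knockout), with the mean (wide line) and SD (error bar) of 3 livers per group. Sirt7 lies at 9.74 in wild type and 2.78 in knockout, and Cxcl14 at 8.35 and 5.31; the other 8 genes did not pass the adjusted threshold.

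Myc itself was close to the expression filter of 4, at 4.22 ± 0.21 in wild-type and 4.07 ± 0.54 in knockout livers (SD, n = 3 each). The difference of -0.15 had a 95% interval of -0.79 to 0.50 (limma adjusted p = 0.92). The 42 tested genes of cytosolic ribosomal proteins had a mean difference of -0.047 (SD over members 0.227; 19 higher, 23 lower), with a camera adjusted p of 0.738, and the sign turned to 0.015 under quantile normalization. Of these genes Rps7 differed by -0.52 (SE 0.26), with -0.17 on another probe set, Rps20 by -0.25 (SE 0.17) and Rps14 by 0.24 (SE 0.20). The Rps20 probe set can match near-identical copies, and a second bright probe set of that gene differed by -0.003. Rps7, Rps20 and Rps14 form a list of reported SIRT7 promoter targets with Nme1 (-0.067, SE 0.24) and Cops2 (-0.15, SE 0.20). The mean difference of that list was -0.15 (camera adjusted p = 0.422), and lay between -0.24 and -0.074 without 1 array.

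The 56 tested genes of ribosome biogenesis and other MYC targets had a mean difference of 0.095 (SD 0.354; 32 higher, 24 lower; camera adjusted p = 0.0667, and adjusted p = 0.632 with an estimated correlation). Limma called 0 members of the 3 lists over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 5 higher members of the MYC target list and 0 of the ribosomal protein list. They were the replicative helicase genes Mcm6 (1.65, SE 0.41), Mcm5 (1.03, SE 0.35) and Mcm7 (0.53, SE 0.18), which are also on the cell cycle list, Ranbp1 (0.58, SE 0.22) and Tfrc (0.48, SE 0.19). Of these only Mcm6 falls under the rule for named genes. Without the 4 members shared with the cell cycle list, an alternative added after seeing the data, the mean difference was 0.028 (52 genes, adjusted p = 0.273). The MYC target list passed the threshold without the filter on dim genes (0.095, adjusted p = 0.0431), with each probe set on its own (0.133, adjusted p = 0.00625), without knockout replicate 2 (0.11, adjusted p = 0.0382) and without wild-type replicate 1 (0.085, adjusted p = 0.045).

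Genes of the endoplasmic reticulum stress and unfolded protein response differed by 0.003 on average over 46 tested members (SD 0.244; 26 higher, 20 lower; camera adjusted p = 0.41). Hspa5, the main chaperone of the endoplasmic reticulum, differed by 0.19 (95% interval -0.29 to 0.67), while another of its probe sets differed by -0.082. Ddit3, which encodes the stress factor CHOP, differed by 0.32 (-0.53 to 1.16), and Xbp1 by 0.20 (-0.37 to 0.77), with -0.13, -0.025 and 0.002 on its other probe sets. Limma called 0 members over all genes and 0 adjusted over the list alone, and 0 had an unadjusted p under 0.05. The sign of the list's mean turned with the stricter filter on dim genes (-0.010) and without wild-type replicate 3 (-0.012) or knockout replicate 2 (-0.026).

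Fasn, the fatty acid synthase gene, was at 10.83 ± 0.15 in wild-type and 11.43 ± 0.35 in knockout livers (SD, n = 3 each), a difference of 0.60 (SE 0.22) with no overlap between the groups that did not pass the threshold (limma adjusted p = 0.76). Fasn is 9 tested genes away from Sirt7 in the gene order. Scd1, a fatty acid desaturase gene, differed by 0.021 (95% interval -0.37 to 0.41) on a probe set with a mean of 12.89, near the top of the range, and by 0.57 on another with a mean of 10.76. The fatty acid transporter gene Cd36 differed by 0.047 (-0.51 to 0.61), with 0.56 and 0.58 on its other probe sets, so the values of both genes depend on the probe set. Pparg differed by -0.19 (-1.03 to 0.65). The 24 tested genes of fatty acid and triglyceride synthesis had a mean difference of 0.063 (SD 0.353; 13 higher, 11 lower; camera adjusted p = 0.433), with 0 members called by limma over all genes, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. The mean difference was 0.12 for lipid droplets, uptake and lipoprotein secretion (26 genes, adjusted p = 0.382), 0.22 for fatty acid oxidation and ketogenesis (35 genes, adjusted p = 0.0667, and adjusted p = 0.744 with an estimated correlation) and -0.061 for cholesterol synthesis (20 genes, adjusted p = 0.738). Without 1 array the lipid droplet list lay between 0.018 and 0.17. The oxidation list lay between 0.061 and 0.36 without 1 array. It passed without wild-type replicate 3 (0.36, adjusted p = 0.00974), wild-type replicate 2 (0.25, adjusted p = 0.0159) or knockout replicate 2 (0.27, adjusted p = 0.0217). It also passed without the filter on dim genes (0.26, adjusted p = 0.0166) and with each probe set on its own (0.25, adjusted p = 0.0079). The synthesis list passed without knockout replicate 2 (0.195, adjusted p = 0.0427) and with each probe set on its own (0.167, adjusted p = 0.0382). Its sign turned without knockout replicate 3 (-0.057), without wild-type replicate 1 (-0.038) and with array weights (-0.204).

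Cell cycle genes rose as a group in knockout livers, by a mean log2 of 1.15 (SD over members 0.644, 2.23-fold), with 32 of 33 tested members higher. Camera gave an adjusted p of 2.39e-21 with its preset correlation, and adjusted p = 0.632 with an estimated correlation. Over all genes limma called 0 members, against 10 adjusted over the list alone, all higher; 20 had an unadjusted p under 0.05. The 4 with the smallest p were Rrm2, a subunit of ribonucleotide reductase (0.93, SE 0.21), Mcm6 of the replicative helicase (1.65, SE 0.41), cyclin A2 (Ccna2, 1.84, SE 0.46) and the transcription factor gene E2f1 (1.37, SE 0.35). The wild-type livers were not alike. The mean deviation of the members from their average over 6 livers was -0.90, -1.27 and 0.44 in wild-type replicates 1 to 3 and 0.58, 0.64 and 0.51 in knockout replicates 1 to 3. Wild-type replicate 3 lay above both other wild-type livers in 30 of 33 members, and the groups did not overlap in 11. Without wild-type replicate 3 limma called 13 members over all genes, all higher, among them Ccna2 (2.46, adjusted p = 0.00613). Among cell type markers, the largest mean difference was that of erythroid and platelet markers, 0.38 (6 genes, adjusted p = 0.0697). The mean difference of lymphocyte markers was 0.14 (16 genes, camera adjusted p = 0.129) and that of histones 0.17 (6 genes, adjusted p = 0.377). Kupffer cell and macrophage markers differed by 0.12 on average (21 genes, camera adjusted p = 0.0875, and 0.0456 without wild-type replicate 1). Without 1 array that list lay between 0.051 and 0.17, with camera adjusted p-values of up to 0.437.

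**Figure D2:**
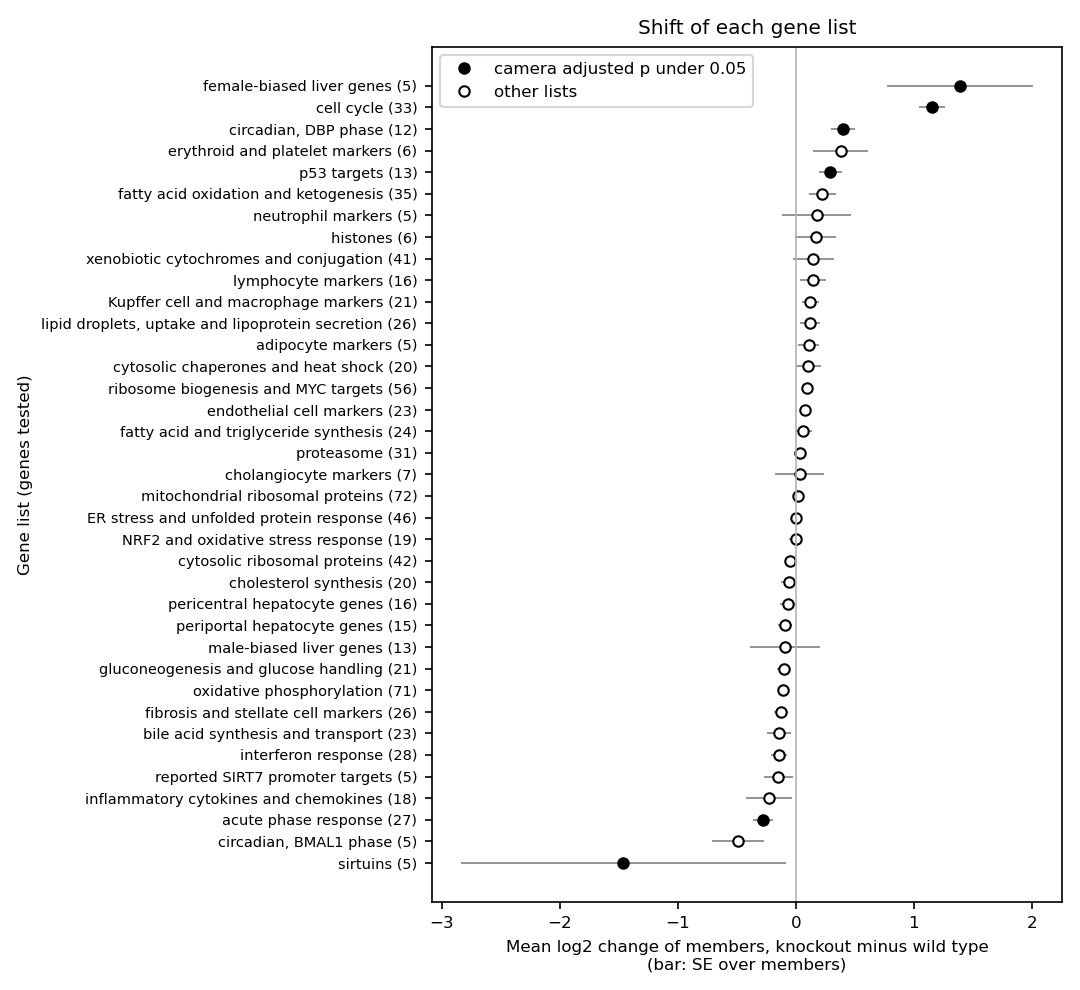
Mean log2 difference, knockout minus wild type, over the tested members of each of 37 gene lists (number of members in parentheses; bar, standard error over members). Filled points mark the 6 lists with a camera adjusted p under 0.05 at the preset correlation; the cell cycle list lies at 1.15 and the cytosolic ribosomal protein list at -0.047.

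Circadian genes that peak with DBP rose by a mean log2 of 0.40 (SD 0.358; 11 of 12 tested members higher; camera adjusted p = 0.00176, and adjusted p = 0.632 with an estimated correlation). Over all genes limma called 0 members, and adjusted over the list alone 2, Nr1d1, the gene of the clock repressor REV-ERB alpha (0.86, SE 0.23), and the mitotic inhibitor kinase gene Wee1 (1.11, SE 0.30). Dbp differed by 0.64 (SE 0.27) and Tef by 0.59 (SE 0.27), with 0.175 on another probe set. The mean deviation was 0.55 in knockout replicate 1 and -0.050 and 0.11 in knockout replicates 2 and 3, against -0.18, -0.39 and -0.034 in wild-type replicates 1 to 3. Genes that peak with BMAL1 had a mean difference of -0.49 (5 genes, 4 lower; adjusted p = 0.0697). They lay between -0.61 and -0.30 without 1 array, and passed without knockout replicate 2 (-0.60, adjusted p = 0.0217) or wild-type replicate 2 (-0.52, adjusted p = 0.0343). The time of day at dissection is not given in the sources used here. The call for the DBP phase was lost without knockout replicate 1 (0.23, adjusted p = 0.0569) and with array weights (0.30, adjusted p = 0.0789).

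The p53 target list rose by a mean log2 of 0.29 (SD 0.348; 11 of 13 tested members higher; camera adjusted p = 0.0243, and adjusted p = 0.637 with an estimated correlation). Limma called 0 members over all genes and 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. That member was Ckap2, a mitotic spindle gene (1.28, SE 0.52), called by limma over all genes without wild-type replicate 3 (1.999, adjusted p = 0.0106). Btg2 differed by 0.55 (SE 0.27), Pmaip1 by 0.37 (SE 0.23) and Sesn2 by 0.34 (SE 0.19). Without 1 array Btg2 lay between 0.25 and 0.75 and Pmaip1 between 0.20 and 0.51. The list, like the cell cycle list, was low in wild-type replicates 1 and 2 (-0.26 and -0.29) and higher in wild-type replicate 3 (0.12). Its call was lost without knockout replicate 1 (0.23, adjusted p = 0.0767), without wild-type replicate 2 (0.22, adjusted p = 0.0749), with the mean of probe sets (0.29, adjusted p = 0.0532) and with the stricter filter on dim genes (0.106, adjusted p = 0.469).

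Acute phase genes fell as a group, with a mean log2 difference of -0.28 (SD 0.454; 22 of 27 tested members lower; camera adjusted p = 0.0243, and adjusted p = 0.715 with an estimated correlation). None of the 27 passed limma over all genes (0) or adjusted over the list alone (0); 3 had an unadjusted p under 0.05. These were the serum amyloid genes Saa1 (-1.04, SE 0.30) and Saa2 (-1.44, SE 0.45), whose probe sets can match each other's transcripts, and Orm3 (-1.45, SE 0.52), while Itih3 differed by -0.50 (SE 0.25). Wild-type replicate 2 had the highest mean deviation, 0.44, against -0.039 and 0.016 in the other wild-type livers and -0.12, -0.22 and -0.081 in the knockout livers. Interferon response genes had a mean difference of -0.14 (28 genes, 20 lower; adjusted p = 0.273). They lay between -0.36 and -0.020 without 1 array and passed without wild-type replicate 1 (-0.36, adjusted p = 2.56e-05). Inflammatory cytokines and chemokines had a mean difference of -0.23 (18 genes; adjusted p = 0.319), and limma called Cxcl14 over all genes and adjusted over the list alone. In that list Cd14 differed by 0.68 (SE 0.19), Vcam1 by 0.60 (SE 0.24) and Cxcl10 by -0.51 (SE 0.24). The acute phase call was lost without wild-type replicate 2 (-0.128, adjusted p = 0.197), without knockout replicate 3 (-0.31, adjusted p = 0.121) and under quantile normalization (-0.229, adjusted p = 0.0692).

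Of the xenobiotic cytochromes and conjugation enzymes, 3 members of the Cyp2c family passed when adjusted over the list alone, against 0 over all genes with limma and 5 at an unadjusted p under 0.05. Cyp2c39 rose by 4.34 (SE 1.05) and Cyp2c38 by 2.78 (SE 0.70), while Cyp2c37 fell by 4.27 (SE 1.08); Cyp2c50 differed by -0.60 (SE 0.17). These genes are close paralogs, so that probe sets can share signal and their values are uncertain. Cyp2c37 was at 9.36 in knockout replicate 1 against 4.16 and 5.53 in the other knockout livers. Cyp2c39 was at 7.35 in wild-type replicate 2 against 2.65 and 3.20 in the other wild-type livers. Over all genes limma called Cyp2c37 without knockout replicate 1 (-5.78, adjusted p = 0.000856) and Cyp2c39 without wild-type replicate 2 (5.81, adjusted p = 0.000565). The list as a whole had a mean difference of 0.15 (41 genes, 21 higher; camera adjusted p = 0.172). It passed without wild-type replicate 2 (0.22, adjusted p = 0.0495) and with each probe set on its own (0.255, adjusted p = 0.0174). Amacr, an enzyme of bile acid synthesis, fell by 0.86 (SE 0.20) and was the 1 gene of its list called when adjusted over the list alone (23 genes tested, 0 over all genes, 4 at an unadjusted p under 0.05); Fgfr4 differed by -1.05 (SE 0.34), Abcc2 by -0.80 (SE 0.28) and Nr0b2 by 0.59 (SE 0.25). Bile acid synthesis and transport had a mean difference of -0.14 (adjusted p = 0.444), and of -0.22 to -0.040 without 1 array.

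Female-biased liver genes had a mean log2 difference of 1.39 (SD 1.38; 5 of 5 tested members higher; camera adjusted p = 0.0441, and adjusted p = 0.637 with an estimated correlation). Limma called 0 members over all genes and 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. Of 12 members on the array 5 were tested, and the groups overlapped in each of them. The mean deviation was -1.90, -0.995 and 0.80 in wild-type replicates 1 to 3. It was 1.62, 1.01 and -0.54 in knockout replicates 1 to 3, so wild-type replicate 3 lay above knockout replicate 3. The mean difference was led by Cyp4a14, a fatty acid hydroxylase gene that PPARA also induces (3.57, SE 1.16), and by Cyp2b9 (1.97, SE 1.26). Cyp17a1 differed by 0.70 (SE 0.97) and Fmo2 by 0.47 (SE 0.33). Without 1 array Cyp2b9 lay between 0.96 and 3.26 and Fmo2 between 0.11 and 0.74. Cyp4a14 passed limma over all genes without wild-type replicate 3 (5.10, adjusted p = 0.0139). Male-biased genes had a mean difference of -0.093 (13 genes, 9 lower; adjusted p = 0.150) and the 3 tested Y-linked genes one of 0.10. The female-biased call was lost without wild-type replicate 1 (0.79, adjusted p = 0.127), knockout replicate 1 (0.93, adjusted p = 0.154) or knockout replicate 2 (1.24, adjusted p = 0.0766), and the mean was 2.14 (adjusted p = 0.00468) without wild-type replicate 3. It was also lost with array centring (adjusted p = 0.0627), quantile normalization (0.0738) and the replicate block (0.051).

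The sirtuin list had a mean difference of -1.46 (5 genes; camera adjusted p = 0.0243, and adjusted p = 0.632 with an estimated correlation), which came from Sirt7. The call was also lost without knockout replicate 3 (adjusted p = 0.164) or wild-type replicate 3 (adjusted p = 0.111), with array weights (0.2) and with the replicate block (0.0513). Without Sirt7 the mean was -0.089 (adjusted p = 0.639), with Sirt1 at 0.21 (SE 0.24), Sirt2 at -0.30 (SE 0.20) and Sirt3 at -0.18 (SE 0.23). Of the 37 lists, camera called 6 at the preset correlation (4 up, 2 down) and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05; fry called 1, the sirtuins. Members past the threshold when adjusted over the list alone were found in 8 of 41 lists, 20 members in all, and in the other 33 lists 0 passed with limma and 34 of 709 tested entries had an unadjusted p under 0.05.

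Hspa1b rose when adjusted over the 20 tested genes of cytosolic chaperones and heat shock alone (0 passed over all genes; 2 had an unadjusted p under 0.05). In that list Fkbp5, a glucocorticoid-induced gene, differed by 1.26 (SE 0.41), Hspb1 by -1.03 (SE 0.63) and Hspa4 by -0.34 (SE 0.22), with 0.013 and -0.25 on its other probe sets. The list's mean difference was 0.11 (camera adjusted p = 0.129). It passed with each probe set on its own (0.18, adjusted p = 0.00526) and turned to -0.004 with array weights. Slc4a1, the anion exchanger of red cells, rose by 1.32 (SE 0.38) when adjusted over the list alone, while Hba-a2 differed by 0.66 (SE 0.27), Hbb-b2 by 0.50 (SE 0.31) and Alas2 by -0.14 (SE 0.26). That list of 6 erythroid and platelet markers had 0 members called over all genes, 2 at an unadjusted p under 0.05 and a mean difference of 0.38 (camera adjusted p = 0.0697). It lay between 0.19 and 0.51 without 1 array. The list passed without knockout replicate 1 (0.51, adjusted p = 0.0126), wild-type replicate 1 (0.44, adjusted p = 0.0383) or wild-type replicate 3 (0.51, adjusted p = 0.0485) and with each probe set on its own (0.63, adjusted p = 0.0079).

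No list of markers of another cell type passed the test with all 6 arrays and the main settings. The mean difference was 0.080 for endothelial cells (23 genes, adjusted p = 0.324), -0.13 for fibrosis and stellate cells (26 genes, adjusted p = 0.350), 0.18 for neutrophils (5 genes, adjusted p = 0.324), 0.11 for adipocytes (5 genes, adjusted p = 0.41) and 0.033 for cholangiocytes (7 genes, adjusted p = 0.61, with a median of -0.004). The 4 tested pancreatic acinar markers had a mean of 0.083 and the 3 muscle and mesothelial markers one of 0.11. Neutrophil markers passed without knockout replicate 1 (0.52, adjusted p = 0.00325). Lymphocyte markers varied within the knockout group, with mean deviations of -0.61, 0.66 and 0.17 in knockout replicates 1 to 3. Without knockout replicate 1 their difference was 0.48 (camera adjusted p = 8.57e-07 at the preset correlation), and without knockout replicate 2 it turned to -0.15 (adjusted p = 0.667). With all 6 arrays their adjusted p was 0.744 by camera with an estimated correlation and 0.846 by fry. The lymphocyte list also passed without wild-type replicate 1 (0.21, adjusted p = 0.0383), without the filter on dim genes (0.17, adjusted p = 0.0475) and with array weights (0.60, adjusted p = 0.00276). Periportal hepatocyte genes had a mean difference of -0.089 (15 genes, camera adjusted p = 0.486), and of -0.137 to -0.045 without 1 array. Pericentral genes had one of -0.069 (16 genes, adjusted p = 0.988, with the test pointing up), and of -0.116 to -0.016 without 1 array. The remaining means were -0.11 for oxidative phosphorylation (71 genes, adjusted p = 0.127), 0.019 for mitochondrial ribosomal proteins (72 genes, adjusted p = 0.41), 0.039 for the proteasome (31 genes, adjusted p = 0.41, with a median of -0.038) and -0.098 for gluconeogenesis and glucose handling (21 genes, adjusted p = 0.279, and -0.185 to -0.038 without 1 array). Oxidative phosphorylation lay between -0.19 and -0.039 without 1 array. It passed without wild-type replicate 1 (-0.165, adjusted p = 0.0153), with array weights (-0.26, adjusted p = 0.00326) and with each probe set on its own (-0.105, adjusted p = 0.0288). NRF2 and oxidative stress genes were at -0.002 (19 genes, adjusted p = 0.606), with a median and test in the other direction and a mean of 0.023 after centring and 0.040 after quantile normalization.

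**Figure D3:**
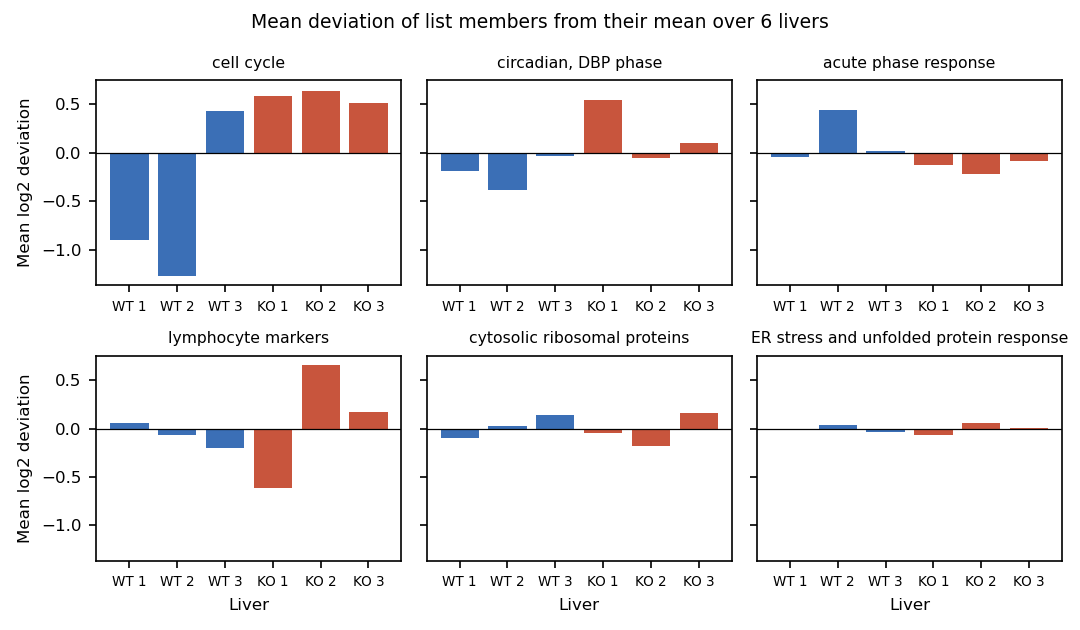
Mean log2 deviation of the members of 6 gene lists from their average over 6 livers, 1 bar per liver (blue, wild type, WT; red, knockout, KO). Wild-type replicate 3 lies at 0.44 for cell cycle genes, beside knockout livers at 0.51 to 0.64, while wild-type replicates 1 and 2 lie at -0.90 and -1.27.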

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

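The fits without Sirt7 in the sirtuin list, without the genes shared by the cell cycle and MYC target lists in either list, and without wild-type replicate 3 and knockout replicate 1 together were chosen after seeing the data; all other alternatives were planned. The cause of a change was not tested unless given. Over 65 named genes and all alternatives, 948 of 1019 values kept their direction and their side of the threshold, 15 reversed, 51 passed only in the alternative (39 of them with array weights) and 5 lost their call. Sirt7 kept its call in all fits except the ordinary 2-sample test (-6.96, adjusted p = 0.0592), which called 0 genes, 0 of them lower. The number of called genes was 2 without the filter, with the stricter filter, with each probe set on its own, with centring and at a 2-fold minimum, 3 with the trended prior and with quantile normalization, 4 (all lower) at an adjusted p of 0.10, and 1 with the mean of probe sets. Array weights, which gave 80.0% of the weight to 2 arrays, called 1748 genes (659 higher, 1089 lower). Without wild-type replicate 3 and knockout replicate 1 together, 46 genes passed. Leaving out 1 array gave 1 to 38 called genes, 0 to 30 higher and 1 to 8 lower.

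The replicate numbers did not pair the samples. The deviations of same-numbered arrays from their group means correlated at -0.09, -0.09 and -0.19. In these deviations no array correlated best with its own number in the other group. In the uncentred values the third replicates of the groups did, with the highest correlation between groups (0.979). With the replicate block 2 genes were called, the female-biased list (1.393, adjusted p = 0.051) and the sirtuins (-1.463, adjusted p = 0.0513) lost their calls, and no other call changed. Besides the lists of ribosomal proteins, MYC targets, stress response and fat synthesis, camera called 6, against 0 with an estimated correlation, 1 with fry, 11 with each probe set on its own and 4 to 10 without 1 array (10 without wild-type replicate 1). An estimated correlation leaves the mean as it is, changes the error and ended the calls for the cell cycle (1.154, adjusted p = 0.632), the DBP phase (0.401, 0.632), p53 targets (0.290, 0.637), the acute phase (-0.280, 0.715) and female-biased genes (1.393, 0.637). Fry asks another question, whether a list's genes move on balance against no change, and gave these lists adjusted p-values of 0.512, 0.512, 0.512, 0.54 and 0.599. The sirtuin call ended with an estimated correlation (-1.463, adjusted p = 0.632), array weights (-1.443, 0.2), without knockout replicate 3 (0.164) or wild-type replicate 3 (0.111) and, by construction, without Sirt7 (-0.089, 0.639); fry gave 0.00105. The cell cycle list passed in the 6 fits without 1 array, at 0.81 to 1.66, and at 1.18 without the genes shared with the MYC target list. Other calls ended for the acute phase under quantile normalization (-0.229), the DBP phase with array weights (0.298), female-biased genes with centring (1.418) and quantile normalization (1.332), and p53 targets with the stricter filter (0.106), which tests fewer genes, and with the mean of probe sets (0.291). The MYC target list passed without the filter (0.095) and with each probe set on its own (0.133), and lay at 0.028 without the genes shared with the cell cycle list. Fat synthesis passed with each probe set on its own (0.167), and fatty acid oxidation both without the filter (0.26) and with each probe set on its own (0.25).

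Signs turned, in lists and genes that did not pass, for ribosomal proteins under quantile normalization (0.015), for the stress response with the stricter filter (-0.010), and for gluconeogenesis with each probe set on its own (0.027). The NRF2 list turned with centring (0.023), each probe set (0.049), the mean of probe sets (0.009) and quantile normalization (0.040). Array weights turned fat synthesis (-0.204), chaperones (-0.004), mitochondrial ribosomal proteins (-0.071), pericentral genes (0.015), the proteasome (-0.048), Myc (0.108), Pparg (0.016) and Cyp17a1 (-1.060). Without 1 array, the lists that passed lay at -0.369 to -0.128 (acute phase), 0.228 to 0.526 (DBP phase), 0.792 to 2.143 (female-biased), 0.216 to 0.421 (p53) and -1.493 to -1.413 (sirtuins). Those that did not lay at -0.136 to 0.030 (ribosomal proteins), 0.055 to 0.117 (MYC targets), -0.026 to 0.035 (stress), -0.057 to 0.195 (fat synthesis), -0.143 to 0.073 (NRF2), -0.002 to 0.208 (adipocytes), -0.020 to 0.123 (cholangiocytes), -0.173 to 0.030 (cholesterol synthesis), -0.057 to 0.164 (endothelial cells), -0.149 to 0.484 (lymphocytes), -0.318 to 0.116 (male-biased), -0.050 to 0.094 (mitochondrial ribosomal proteins), -0.026 to 0.518 (neutrophils) and -0.032 to 0.113 (proteasome). Named genes whose sign turned lay at -0.365 to 0.082 (Alas2), -0.152 to 0.202 (Cd36), -0.321 to 1.548 (Cyp17a1), -0.377 to 0.149 (Myc), -0.244 to 0.132 (Nme1), -0.484 to 0.139 (Pparg), -0.014 to 0.066 (Scd1) and -0.010 to 0.357 (Xbp1). Signal over background limits Myc and Xist, whose values lie near or under the expression filter. It also limits the size of differences with a group mean under 4: in knockout for Sirt7 (2.78), Cd300ld (2.99), Dct (2.68) and Clec2h (2.33), and in wild type for Cyp4a31 (3.32), Cyp2b9 (3.52), E2f1 (3.83), Pmaip1 (3.885) and Fmo2 (3.95).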

Other observations

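The tests of genes near Sirt7 and of lymphocyte, macrophage and erythroid markers were chosen only after the results were seen; the tests of young liver genes and of other splits of the arrays were set before theirs. The genes named in the next paragraph were chosen after their values were seen, and none of them passed the adjusted threshold with all 6 arrays. Leaving out 1 array, limma called Dct without wild-type replicate 2 (-6.05, adjusted p = 0.00399), and Clec2h (-6.46, adjusted p = 0.00178) and Cyp4a14 (5.10, adjusted p = 0.0139) without wild-type replicate 3.

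Of single genes that PPARA can induce in liver, Cyp4a31 differed by 2.62 (SE 0.58, limma adjusted p = 0.544) and Vnn1 by 1.43 (SE 0.52, adjusted p = 0.76). Angptl4 differed by 1.06 (SE 0.40, adjusted p = 0.763) and Pex11a by 0.53 (SE 0.20, adjusted p = 0.77). In the fatty acid oxidation list, which holds many such genes and did not pass (adjusted p = 0.0667), 22 of 35 members were higher and 13 lower, among them Crat at 0.59, Acot1 at 0.45, Ehhadh at 0.046, Pdk4 at 0.022 and Cpt2 at -0.47. In wild-type replicates 1 to 3 Cyp4a14 was at 5.84, 7.69 and 11.37, against a knockout mean of 11.86 ± 0.76 (SD), so the third wild-type liver again lay near the knockouts. Of the interferon-induced genes, Oasl2 differed by -0.83 (SE 0.23, adjusted p = 0.706), Igtp by -0.78 (SE 0.22, adjusted p = 0.725) and Ifih1 by -0.72 (SE 0.23, adjusted p = 0.746). Clec2h, a C-type lectin gene, differed by -4.92 (SE 1.12, adjusted p = 0.544) and Dct, known from melanin synthesis, by -4.75 (SE 0.99, adjusted p = 0.487), with wild-type SDs of 2.72 and 2.42. C1qa, a complement gene of macrophages, differed by 1.05 (SE 0.35, adjusted p = 0.746), and the clock gene Npas2 by -1.27 (SE 0.40, adjusted p = 0.746).

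Several genes with the smallest p lie near Sirt7 on its chromosome: 5 of the 20 genes with the smallest p other than Sirt7 (Cd300ld, Pcyt2, Usp36, Mcrip1 and Hexdc) fall within 100 tested genes of it in the order of assembly GRCm38.p6, where 0.29 would be expected (exact hypergeometric p = 7.44e-06, on a pattern noticed first). Of 53 other stretches of 120 tested genes, 0 held as many of these 20 genes and none more than 1, but the stretch around Sirt7 was picked for them. It held 14 genes with an unadjusted p under 0.05, and 1 of the 53 (1.89%) held as many, with 16, so clustering that occurs anywhere is not excluded. Candidate explanations are DNA of another strain carried along with the targeted allele and an effect of the allele on the genes beside it, and the shares behind them stay open: 11% of 100 genes at ranks 11 to 100 (11 genes, Fisher's exact p = 0.0954) and 15% of the 20 nearest genes (3 genes, Fisher's exact p = 0.133), against 6.4% on other chromosomes. Cd300ld, 76 genes away, and Usp36, 27 away, lie outside the nearest genes, while Pcyt2 is adjacent, so the 2 explanations cannot be told apart with these counts. An effect of SIRT7 loss itself on these genes was not tested and stays open, and the strain of the mice is not given in the sources used here.

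Cell cycle genes were higher in the knockout group by 1.15 on average, but wild-type replicate 3 shared their level. More lymphocytes or macrophages in the knockout livers would raise their markers, and these differed by 0.144 (16 genes) and 0.123 (21 genes), 1.01 and 1.03 less than the cell cycle genes. With the spread over livers these gaps (SE 0.68 and 0.54) are under 2 SE. The lymphocyte mean runs from -0.149 to 0.484 without 1 array. By liver, lymphocyte markers were lowest in knockout replicate 1 (-0.609) and wild-type replicate 3 (-0.205), where cell cycle genes were high (0.583 and 0.436). The markers peaked in knockout replicate 2 (0.656), so they did not follow the cell cycle genes from liver to liver. Macrophage markers were lowest in wild-type replicate 3 (-0.092) and highest in knockout replicate 1 (0.205). Dntt (1.46, with 1.21 and 1.43 on its other probe sets) and C1qa (1.05) differed about as much as the cell cycle genes. Both were picked for their values, and 0 of 16 lymphocyte and 2 of 21 macrophage markers had an unadjusted p under 0.05. As a group difference neither cell type is excluded. Erythroid and platelet markers differed by 0.38 (6 genes), 0.775 less (SE 0.407 over livers), and stay open too. Younger livers in the knockout group stay a candidate explanation that could not be decided, with 10 young liver genes at 0.059 on average (SE over members 0.186, not over livers, and 4 higher). SIRT7 loss was not tested apart from other differences between these samples. Splits that set wild-type replicates 1 and 2 with knockout replicate 1, 2 or 3 against the rest gave shifts of 1.06, 1.02 and 1.10 in size. No split that parted wild-type replicates 1 and 2 gave more than 0.211. The shift thus followed these 2 livers, whichever array joined them.

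The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. As many called genes as the real 2 came in 1 of the 10 splits, the real one, and the highest other count was 1. Sirt7, the gene removed in the knockout, is 1 of these 2. This count and the sirtuin shift below were therefore largely set by the design. As many lists as the real 6 came in 5 of 10 splits, and another split gave 9. The list shifts below are those of MYC targets, fat synthesis, ribosomal proteins, the stress response and the lists called in the real split. Choosing called lists favours the real split. A list shift as large as the real one came in 1 of 10 splits for the cell cycle (1.15; highest other 1.10), MYC targets (0.095; 0.076), the acute phase (-0.28; size 0.252) and the sirtuins (-1.46; size 0.564). It came in 2 for the DBP phase (0.40; 0.412) and female-biased genes (1.39; 2.29), in 3 for p53 targets (0.29; 0.319), in 7 for fat synthesis (0.063; 0.284), in 8 for ribosomal proteins (-0.047; size 0.218) and in 10 for the stress response (0.003; 0.067).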
